A study of Mus musculus with 6 samples.

How the data were processed

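RNA of the mouse chondrogenic cell line ATDC5, a line derived from a teratocarcinoma that is widely used as a model of cartilage formation, was measured on 6 one-colour Agilent arrays that carry probes for messenger RNAs and long non-coding RNAs (lncRNAs). Messenger RNA was purified by removing ribosomal RNA and amplified by random priming along the whole transcript, per the labels' protocols. The submitters' text names Affymetrix arrays and a biotin label, whereas the protocol and the file headers describe Agilent one-colour arrays with the dye Cy3. Samples were grouped by their titles into 3 differentiated and 3 undifferentiated samples. Differentiation was induced for 14 days with 1% ITS, a supplement of insulin, transferrin (5.5 µg/ml) and sodium selenite (5 ng/ml), per the labels' protocols. The insulin concentration printed in the labels is zero, which cannot be resolved here, and the culture time of the undifferentiated cells is not stated there. Nothing in the labels says that the replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

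The deposited scanner files hold spot intensity values written by Agilent Feature Extraction, version 11.0.1.1, per the file headers and the submitters' processing notes. The processed signal was background-subtracted and detrended within each array by that software and was not scaled between arrays. No spot was saturated. The deposited value table of the series holds log2 values per probe. Its 6 columns have medians of 5.751 or 5.752, as quantile normalization gives, and each correlated at 0.9998 or more with the log2 scanner signal of its own array, so its scale and direction are settled; whether a further filter was used is not given in the sources used here. It was used as an alternative only.

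Each array held 61500 non-control spots of 60930 probes. Spots that Feature Extraction flagged as outliers (59 to 162 per array) were left out, and spots of one probe were averaged on the log2 scale. Each array's 75th percentile of log2 processed signal was subtracted, so that levels below are log2 values relative to that percentile. A probe was kept if it was well above background, by Feature Extraction's own test, on at least 3 of the 6 arrays whatever their group. The 15 negative-control probes were left out, which left 60915 probes, of which 41838 (68.7%) were kept. The arrays' number limits the precision of every value.

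The probe names are the array maker's own, and the files do not pair them with genes. Only 15 probes carry a RefSeq transcript accession. All 15 were named through RefSeq symbols of assembly GRCm38.p6 without version numbers, and no coordinates were used because the array's design rests on an older build. The other 60900 probes stay unnamed here. Of the 40 gene lists fixed before the data were examined, only the housekeeping list had at least 3 measured members, with 9, and the other 39 could not be tested. The planned division into coding genes and lncRNAs was replaced by what the probe names say. The 15 accession-bearing probes stand for the coding genes and the 732 probes named as mouse lincRNAs (long intergenic non-coding RNAs) for the lncRNAs. The rule for named items, fixed before the data were examined, took the 6 coding genes and 4 lncRNAs with the largest rise and as many with the largest fall. They had to be changed, well above background on all 6 arrays and without overlap between the groups. The rule also took some fixed cartilage genes, members of the lists, and Actb. Without gene names it was limited to 1 rise and 1 fall among the unnamed probes and 1 of each among the mouse lincRNA probes, and of the fixed genes only Actb could be given. All 15 named genes are reported, which is wider than the rule.

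Differences were tested with limma (lmFit and eBayes, version 3.58.1, R 4.3.3), two-sided, on all 6 arrays with no block, with Benjamini-Hochberg adjustment over the kept probes and a threshold of 0.05. The housekeeping list was tested with camera against all other kept probes, with the preset correlation of 0.01, where a table with 1 probe per gene had been planned. A test was run on simulated data with the real probe means and 200 changed probes among 41838. The noise had limma's moderated probe variances, which are drawn towards a common value and so spread less than the real ones. The test's results were as follows. It recovered 53.0% of 2-fold and 95.0% of 4-fold changes, with 11 false calls, and called 0 probes when nothing was changed. The simulated noise was independent between probes and held no slide, scan or array effects. The real fit called 5563 probes, many more than 200, so these rates do not describe that fit. Alternatives were normexp background correction on the median signals (the mean signal that was planned is not a column of these files) with an offset of 50, quantile normalization, a percentile over probes detected on all arrays, the authors' value table, another or no filter on dim probes, blocks for replicate number and slide, an intensity trend with a robust prior, a 2-fold threshold, and leaving out each array. Fits with the scan as a block and within 1 slide or 1 scan were added after seeing the data.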

Results

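The data comprised 6 arrays, 3 of ATDC5 cells induced towards cartilage for 14 days and 3 of undifferentiated ATDC5 cells. Between 38109 and 43277 of 60915 probes per array (62.6% to 71.0%) were well above background. The lowest number was on differentiated array 1 and the highest on undifferentiated array 2. The median signal of non-control spots ranged from 44.0 to 60.5 intensity units, against 3.33 to 4.40 on the negative-control probes. All 3 differentiated arrays and undifferentiated array 3 lay on slide 1, and undifferentiated arrays 1 and 2 on slide 2. Differentiated array 1 was scanned alone, and differentiated arrays 2 and 3 together with undifferentiated array 3. Undifferentiated arrays 1 and 2 had a scan of their own, so they shared neither slide nor scan with a differentiated array. Array pairs of one group correlated at 0.9816 to 0.9925 over the kept probes, and pairs from different groups at 0.9598 to 0.9712. The median absolute log2 differences overlapped, at 0.118 to 0.282 for pairs of one group and 0.257 to 0.366 for pairs from different groups. Differentiated array 1 lay 0.282 from differentiated array 3 and 0.272 from undifferentiated array 1.

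The comparison of differentiated with undifferentiated cells asks which messenger RNAs and lncRNAs change when ATDC5 cells are taken through chondrogenic induction. Of the 41838 probes tested, 5563 (13.3%) changed at an adjusted p under 0.05 in limma's test, 2258 being higher and 3305 lower after differentiation. The changes above 2-fold ran the other way. Among changed probes, 1201 rose and 1041 fell by 2-fold or more, 446 rose and 148 fell by 4-fold or more, and 185 rose and 39 fell by 8-fold or more. At 16-fold or more, 87 probes rose and 9 fell. The share of rises among changes of 8-fold or more was 82.6% (exact 95% interval 77.0% to 87.3%, which treats probes as independent, although several can read 1 transcript). It was 81.3% with the slide as a block. There the group difference rests on undifferentiated array 3 as the only undifferentiated one, since slide 2 held no differentiated array.

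**Figure D1:**
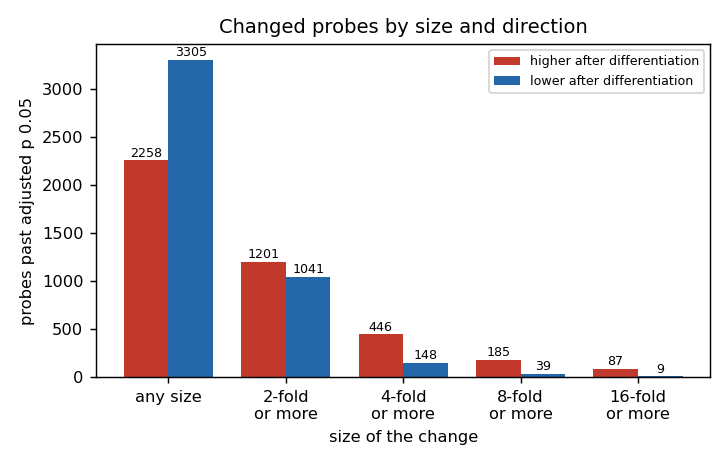
Number of probes past an adjusted p of 0.05 (vertical axis) by minimum size of the change (horizontal axis), for probes higher (red) and lower (blue) after differentiation. Lower probes outnumber higher ones over all sizes (3305 against 2258), and higher probes outnumber lower ones from 2-fold upward, reaching 87 against 9 at 16-fold or more.

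Part of these large changes involved probes that were not well above background in one group, for which a fold is only a lower bound. With the dim group set to the lowest signal of any probe well above background on the same array (or the probe's own, where higher), 133 probes were higher and 25 lower by at least 8-fold, and 56 were higher and 4 lower by at least 16-fold. In all, 188 probes were well above background on all 3 differentiated arrays and on 0 undifferentiated arrays, and 181 of them were called higher. The reverse held for 456 probes, of which 200 were called lower. Detection per array also differed, at 62.6% to 67.5% on the differentiated and 66.1% to 71.0% on the undifferentiated arrays. The larger count therefore need not mean that transcripts were switched off. Detection and calls rest on the same arrays, so the shares called are no separate support. Among probes well above background on all 6 arrays, 68 rose and 14 fell by 8-fold or more.

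Among changed probes that were well above background on all 6 arrays and whose groups did not overlap, the unnamed probe ASMM10P030742 had the largest rise. Its log2 level was 6.67 ± 0.177 (SD, n = 3) in differentiated and -1.67 ± 0.145 (SD, n = 3) in undifferentiated cells, a log2 difference of 8.34 with a standard error of 0.147, or 324-fold (limma, adjusted p = 1.65e-06). The largest fall within this same set was that of ASMM10P033891, from 1.964 ± 0.235 to -2.17 ± 0.109 (SD, n = 3 each), a log2 difference of -4.14 with a standard error of 0.157, or 17.6-fold (limma, adjusted p = 2.27e-05). The files do not pair either probe with a gene. With the slide as a block, limma gave 8.40 and -4.30 for them (adjusted p = 0.000121 and 0.000783).

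The number of changed probes rested on the arrays used. It was 3165 without differentiated array 1, 2919 without differentiated array 2, 3068 without undifferentiated array 2 and 3334 without undifferentiated array 3. With the slide as a block, limma called 3209 probes, 1913 higher and 1296 lower, so that the majority of calls turned from lower to higher. Within slide 1 (3 differentiated arrays against 1 undifferentiated) it called 2430, 1664 of them higher, and 1584 of these were among the 5563. With the scan as a block it called 1519, 1063 of them higher. Within the scan that held both groups (2 differentiated arrays against 1) it called 2347, 1609 of them higher. In the fits within slide 1 and within that scan, the lone undifferentiated array was assumed to vary like the differentiated ones.

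**Figure D2:**
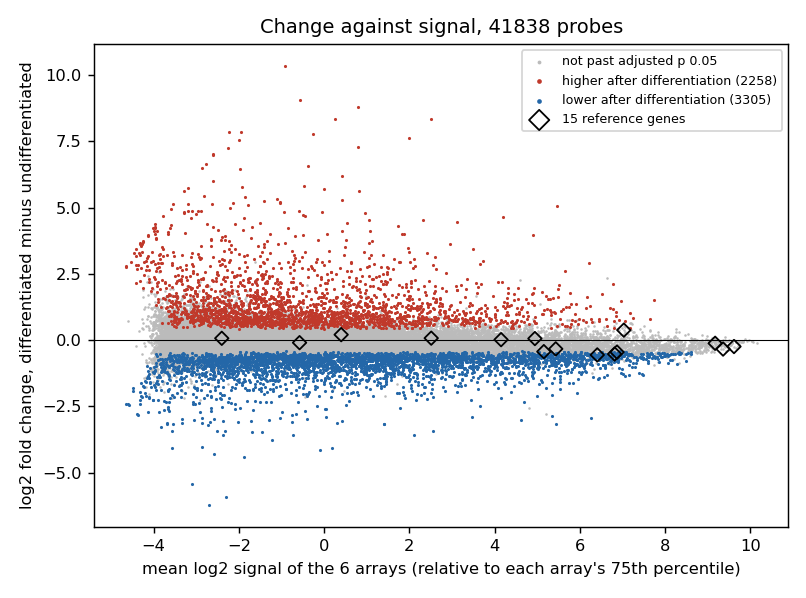
Log2 fold change (differentiated minus undifferentiated, vertical axis) against mean log2 signal of the 6 arrays relative to each array's 75th percentile (horizontal axis), 1 point per kept probe. Red and blue points passed an adjusted p of 0.05 (2258 higher, 3305 lower), grey points did not, and diamonds are the 15 named genes.

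The excess of lower calls lay among bright probes. In the brightest decile of the kept probes 736 were lower and 149 higher, whereas in the dimmest decile 217 were lower and 204 higher. The median log2 fold change of the brightest decile was -0.23, against -0.05 over all kept probes. The median of this decile per array was 5.27 ± 0.084 (SD, n = 3) in differentiated and 5.50 ± 0.150 (SD, n = 3) in undifferentiated cells, which an exact permutation test over the 6 arrays did not separate (two-sided p = 0.2; the smallest p this design allows is 0.1). Quantile normalization, which gives every array the same distribution and so evens out the brightest probes by construction, turned the direction in this decile, with 407 probes higher and 341 lower and a median of 0.0059. The authors' value table, whose columns have near-equal medians, gave 387 higher and 386 lower. The lower level stayed with the normexp background (median -0.27, 191 higher and 1261 lower) and the percentile over detected probes (-0.19, 186 higher and 732 lower), and with the slide as a block the median was -0.36, with 47 higher and 281 lower.

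The 15 named genes are mostly genes in general use as expression references, each read by 20 spots per array. One of them passed the test over all probes. Hprt, the purine salvage enzyme hypoxanthine phosphoribosyltransferase, was 1.44-fold lower after differentiation, at 6.55 ± 0.169 against 7.08 ± 0.1 (log2, SD, n = 3 each), with a log2 difference of -0.53, a standard error of 0.138 and an adjusted p of 0.0499 in limma. This call was lost with quantile normalization (log2 difference -0.21, adjusted p = 0.347 in limma), the authors' value table (-0.25, adjusted p = 0.225) and the slide block (-0.60, adjusted p = 0.147). Leaving out differentiated array 3 kept the call (adjusted p = 0.0228 in limma), and leaving out any other array ended it (0.0659 to 0.176). Over all alternatives its adjusted p in limma ranged from 0.0116 to 0.447. Tfrc, the transferrin receptor through which cells take up iron, had the largest difference of the 15 at -0.56 (standard error 0.160), from 6.69 ± 0.210 to 6.13 ± 0.170 (SD, n = 3 each), and missed the threshold (limma, adjusted p = 0.0652). It passed under other settings, among them the normexp background (adjusted p = 0.0153 in limma, the lowest of the alternatives, the highest being 0.332 within the shared scan). Adjusted over the 15 genes alone, limma called 0 of them, and the unadjusted p was under 0.05 for 6. Over all 41838 kept probes it was under 0.05 for 10915.

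The chaperone gene Hsp90ab1 (log2 difference -0.45, standard error 0.185), the cytoskeletal genes Actb (-0.43, 0.174) and Tuba1b (-0.34, 0.136), the ribosomal protein gene Rpl13a (-0.33, 0.142), the cyclophilin gene Ppia (-0.24, 0.120), the glycolytic gene Gapdh (-0.12, 0.130) and the glycerol kinase gene Gk (-0.10, 0.157) had values below zero without passing limma's test (adjusted p from 0.167 for Actb to 0.751 for Gk). Without undifferentiated array 1, Actb passed at -0.60 (adjusted p = 0.0454 in limma, the highest without another array being 0.384). Values above zero were found for B2m, the light chain of class I histocompatibility molecules (0.38, standard error 0.129, adjusted p = 0.113), G6pd2 (0.21, 0.133), the TATA-binding protein gene Tbp (0.07, 0.167), Ldhal6b (0.07, 0.118), the lysosomal enzyme gene Gusb (0.06, 0.163) and the RNA-binding protein gene Nono (0.02, 0.186). For B2m the 3 differentiated arrays, at 7.22 ± 0.034, all lay above the 3 undifferentiated ones, at 6.84 ± 0.157 (SD, n = 3 each), and it passed with quantile normalization (0.68, adjusted p = 0.00822 in limma) and the authors' value table (0.64, adjusted p = 0.00926). Groups without overlap, in either direction, were found for 32.9% of the kept probes. With the slide as a block B2m stood at 0.21 (adjusted p = 0.571 in limma), and over all alternatives its adjusted p in limma ranged from 0.00822 to 0.855. Gapdh turned to 0.04 with quantile normalization and 0.05 with the authors' value table, Nono to -0.02 with the normexp background, and Nono and Gusb to -0.08 and -0.02 with the slide block. G6pd2 and several others of these genes have near-identical relatives, and how far the probes tell them apart is not known here.

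**Figure D3:**
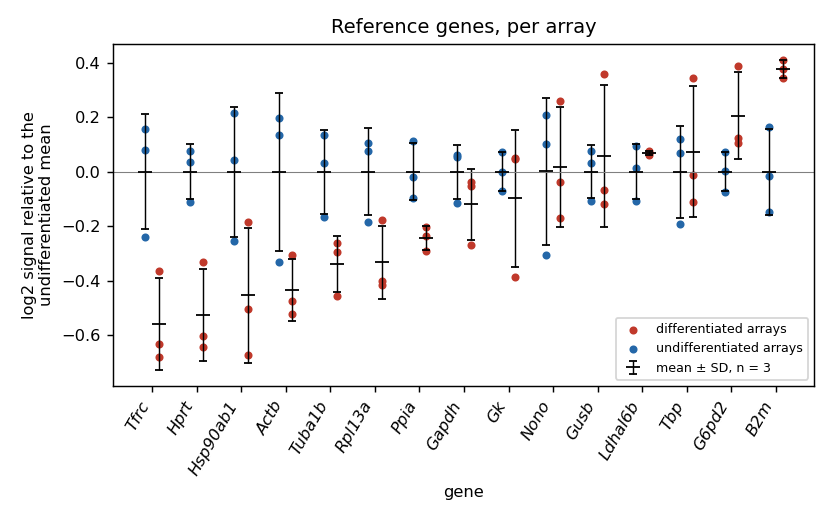
Log2 signal of the 15 named genes per array relative to the undifferentiated mean of each gene (vertical axis), for 3 differentiated (red) and 3 undifferentiated (blue) arrays, with black lines for the mean ± SD (n = 3). Hprt is the gene that passed the threshold, and Tfrc and B2m mark the ends of the range at -0.56 and 0.38.

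The housekeeping list had 9 measured members, of which 1 was lower (Hprt), 0 were higher and 8 did not pass. Adjusted over the list alone, 2 were lower, which were Hprt and Tfrc. The list's median log2 difference was -0.24, and limma's camera did not separate it from the other probes (adjusted p = 0.204; adjusted p = 0.583 with an estimated correlation; with 1 list tested the adjusted p equals the unadjusted one). It passed with the normexp background (adjusted p = 0.0349 in limma's camera), the lowest of the alternatives, the highest being 0.969 with the authors' value table. With the slide as a block limma's camera gave an adjusted p of 0.0768, within slide 1 of 0.07 and within the shared scan of 0.166. In limma's fry, which does not compare the list with other probes, the adjusted p was 0.156 for a shift of the list in 1 direction and 0.0016 for changes of its members in either direction. Of all 41838 kept probes, 10915 had an unadjusted p under 0.05 in limma. The small p for either direction is therefore not shown to be particular to this list. Separate control spots for the 3' and 5' parts of Gapdh and of Pgk1, a glycolytic kinase gene, gave the signal at 2 places of each transcript. Whether their difference reflects RNA integrity after amplification by random priming is not known here. The difference of 5' minus 3' log2 signal was -2.60 ± 0.247 in differentiated and -2.74 ± 0.194 in undifferentiated cells for Gapdh (SD, n = 3 each), with a two-sided exact permutation p of 0.5. For Pgk1 it was -8.31 ± 0.063 and -8.52 ± 0.460 (exact permutation p = 0.5). The Pgk1 3' spots alone were lower on all 3 differentiated arrays, at 7.71 ± 0.208 against 8.18 ± 0.190 (SD, n = 3 each; exact permutation p = 0.1, the smallest possible).

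Of 732 probes whose names mark them as mouse lincRNAs, 328 (44.8%) were kept, each for another transcript name. Among these 5 were higher and 3 lower, or 2.44%. Random sets of 328 unnamed ASMM10P probes matched on mean signal held 26 to 48 calls (the middle 95% of 10000 sets, median 36). MM9LINCRNAEXON11274+_P1 rose 2.99-fold, from -0.20 ± 0.332 to 1.39 ± 0.081 (SD, n = 3 each), with a log2 difference of 1.58, a standard error of 0.184 and an adjusted p of 0.0022 in limma. mouselincRNA1606-_P1 was 2.69-fold lower at -1.43 (standard error 0.227, limma, adjusted p = 0.00776), from 5.61 ± 0.093 to 4.18 ± 0.449 (SD, n = 3 each), and it missed the threshold with the slide block (-1.51, adjusted p = 0.0521 in limma), the scan block (0.0758) and within slide 1 (0.0921), in a range of 0.000651 to 0.0921 over all alternatives. The slide block gave 14 calls in this class, 12 higher and 2 lower, where matched sets held 17 to 36. There were 15 calls within slide 1 and 16 within the shared scan, where matched sets held 13 to 30 and 14 to 32. The count fell to 5 without differentiated array 1, undifferentiated array 2 or undifferentiated array 3.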

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

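The signals below were found after seeing the data. Of the 22 spike-in control probes (10 of the E1A set and 12 of the ERCC set), for which no spike-in RNA is named in the labels' protocols, 4 were well above background on all 6 arrays. ERCC-00062_278 had a median signal of 199.0 intensity units, ERCC-00104_60 of 35.3, ERCC-00012_90 of 33.5 and ERCC-00097_63 of 30.6, against 3.33 to 4.40 on the negative-control probes. Their differences between differentiated and undifferentiated arrays were -0.12, -0.14, -0.10 and -0.24 on the log2 scale.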

How the results depend on the processing

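Fits by scan and within 1 slide or scan were chosen after seeing the data. The count of 5563 changed probes lay within 1.5 times of its value under the alternatives other than the slide block (3209), the scan block (1519), slide 1 alone (2430), the shared scan alone (2347), the 2-fold threshold (2242), and leaving out differentiated array 1 (3165) or 2 (2919) or undifferentiated array 2 (3068) or 3 (3334), with a range of 2919 to 5944 when 1 array was left out. Of these 5563 calls, 1 changed sign under the normexp background and 1 under the authors' value table, and 0 under each other setting. The other filters, the replicate block, the intensity trend and the 2-fold threshold left log2 differences of probes without missing values as they were. Almost no sign could change there. The remaining fits used arrays that had also made the calls, so this agreement is no separate support. The share of lower calls, 59.4%, fell below the share of higher calls with the slide block (40.4%), the 2-fold threshold (46.4%), the scan block (30.0%), slide 1 alone (31.5%) and the shared scan alone (31.4%); it was 51.6% with quantile normalization, 52.7% with the authors' table and 50.8% to 67.2% without 1 array. The share of rises among changes of 8-fold or more was 79.6% to 85.5% without 1 array and 91.4% with normexp. The cause of these shifts was not tested. Same-numbered samples deviated from their group means with correlations of 0.14, -0.087 and 0.034, which is no clear sign of pairing by replicate number. With 3 samples per group, pairing is not excluded. Of the 6 samples, 3 correlated best with their own number. With the replicate number as a block, 3985 probes were called, and of the named genes and probes only Hprt lost its call (adjusted p = 0.084 in limma). The count of named coding genes was 1 in the fit reported, which was Hprt, lower. With quantile normalization and with the authors' table it was also 1, but there the gene was B2m, higher. The count was 2 with normexp, the percentile over detected probes, the filter on all 6 arrays and the intensity trend. It was 0 with no filter, the replicate, slide and scan blocks, slide 1 alone, the shared scan alone and the 2-fold threshold, and 0 to 2 without 1 array. The count of mouse lincRNA probes, 8, was 5 without a filter, 14 with the slide block, 4 at 2-fold, 15 on slide 1, 16 in the shared scan, and 5 to 12 without 1 array. The housekeeping list passed under normexp alone (1 list; limma's camera, adjusted p = 0.0349), and its adjusted p ranged from 0.0569 to 0.403 without 1 array. Log2 differences that turned sign, none of them past the threshold, were Gapdh with quantile normalization (0.0414) and the authors' table (0.048), Nono with normexp (-0.0158), the slide block and slide 1 (-0.0824), Gusb with the slide block and slide 1 (-0.0187), and, without 1 array, Gk (-0.171 to 0.0481), Gusb (-0.0917 to 0.146), Nono (-0.136 to 0.12) and Tbp (-0.0611 to 0.166). Scaling moved the median of all kept probes by at most 0.0615 log2 units. Averaging several probes of a gene was not run, since each named gene had 1 probe. Near background a fold is only a bound: 14667 probes were above background on no array.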

Other observations

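The tests of the slide, of the lincRNA-named probes within slides and scans, and of consecutive probe numbers were chosen after their results had been seen in part. The others were set out before they were run, but most of them concern patterns found in these same data. The array also held 1104 probes named as human lincRNAs, whose targets in the mouse are not given in the sources used here. Of these, 453 (41.0%) were kept and 10 changed, 3 higher and 7 lower, where signal-matched sets of ASMM10P probes held 38 to 64 calls. A further 923 probes named ASMM10UP gave 379 kept probes with 15 higher and 15 lower, against 32 to 56 calls in matched sets; with the slide as a block it had 26 calls against 20 to 40. Differentiated arrays 1 and 2 were the closest pair, with a median absolute difference of 0.118 log2 units against 0.15 to 0.282 for the other pairs of one group. They differed by over 3 standard errors of the spot means for 7 of the 15 named genes, against 11 to 14 genes for the other pairs. Spot noise leaves out the differences between hybridisations, so this does not show whether they hold separate samples. They were counted as 2 because the labels list them so, and the count of changed probes was 3165 without the first and 2919 without the second.

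The split of the arrays by group gave 5563 calls, and the highest count of the other 9 splits was 0, but 10 splits cannot give a share under 0.05 (1 of 10 was as large). A slide or scan effect shared by the differentiated arrays would draw undifferentiated array 3, which lay on their slide and in the scan of 2 of them, towards them. Among probes called higher without that array, its median position was 0.0897 of the way from the other undifferentiated arrays to the differentiated ones (95% interval 0.0793 to 0.101 from a bootstrap over probes, which leaves out the spread between arrays), and among probes called lower it was -0.0476 (-0.0596 to -0.0369). The undifferentiated arrays of the other slide, placed likewise, lay at -0.00345 (array 1) and 0.056 (array 2) among higher calls and at 0.171 and 0.00775 among lower calls. With the slide as a block 47.1% of the higher and 35.5% of the lower calls stayed called in the same direction, and with the scan as a block 30.6% and 12.5%. Of all kept probes, these fits called 7.67% and 3.63%. Array 3 is the only undifferentiated array beside differentiated ones there, and its values also helped to make the calls. Some retention was therefore built in, so these shares are no separate support. The positions of array 3 argue against slide or scan as the whole source of either set of calls, although they rest on 1 array. A contribution of slide or scan to part of the calls remains open, as does the differentiation itself.

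Large rises outnumbered large falls. A log2 shift of 0.78 would be needed to even out the changes of 8-fold or more, whereas the scalings tried moved the median of all kept probes by at most 0.0615 and set the median of the brightest decile between -0.27 and 0.0059. Under these scalings 83.1% to 91.4% of such changes were rises, the last with normexp on 53 rises and 5 falls. This argues against the choice among these scalings as the cause. All of them align the arrays on their own signals, so a shift common to most probes is not excluded. Among probes well above background on all 6 arrays, 82.9% of such changes were rises (exact 95% interval 73.0% to 90.3%). The excess of rises was therefore not confined to probes at the floor of dim spots. This filter leaves out falls that ended at the floor, as well as rises from it. A dim probe also cannot fall 8-fold and stay above the floor, so this test does not exclude the floor. The differentiation itself remains a candidate explanation. It is a hypothesis found and examined on the same data, and without gene names it could not be tied to any gene group. The labels give no culture time for the undifferentiated cells, so differentiation cannot be told apart from time in culture or the supplement.

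Probes named as lincRNAs were called less often than signal-matched ASMM10P probes in the fit over all 6 arrays without a block. With the replicate number as a block, 8 calls among mouse-named probes lay below 18 to 38, and 9 among human-named ones below 28 to 50. With any 1 array left out, the calls of both classes also lay below their matched ranges. Fits by slide or scan showed such a shortfall only in part. Those within slide 1 or the shared scan also held just 1 undifferentiated array, so what changed the result is not settled. Dim signal is argued against as the cause in that fit, where the 8 calls among mouse-named probes lay below the 26 to 48 of matched sets. Within slide 1 the 15 calls lay inside the 13 to 30 of matched sets, as did 16 within the shared scan (14 to 32) and 8 with the scan block (8 to 22), while 14 with the slide block lay below 17 to 36. For human-named probes the 36 calls with the slide block, 33 within slide 1 and 38 within the shared scan all lay inside their matched ranges (26 to 49, 20 to 41 and 21 to 42). Mouse-named probes were kept 3.78 percentage points more often than human-named ones (95% interval -0.85 to 8.4; Fisher's exact p = 0.11) and in the fit without a block were called about as often (2.44% and 2.21%; Fisher's exact p = 0.81), so it is not shown that the mouse-named probes read mouse lincRNAs, and slide or scan, unspecific signal and a property of the transcripts all remain open.

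The median log2 difference of the 15 named genes, -0.12, lay at percentile 78.2 of lists matched on mean signal (middle 95% from -0.41 to -0.0068, median -0.20), so the values below zero among these genes may be part of the lower level of bright probes in general.

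Probes with consecutive numbers tended to change together. A probe was called in 18.5% of cases when the number before it was called and in 12.9% when it was not, and 69.5% of 738 consecutive pairs that were both called changed in the same direction. The correlation of log2 fold changes across probes, which are not independent, was 0.075 (Spearman) at a gap of 1 number, 0.039 at 2 and 0.00025 at 50. Consecutive numbers lay as far apart on the slide as random pairs (median 1473 against 1475 scanner units). Among the 14731 consecutive pairs whose spots lay farther apart than the median distance, the correlation was 0.062, against -0.019 for random pairs as far apart, a difference of 0.081 (bootstrap 95% interval 0.058 to 0.11). This argues against neighbouring spots as the whole cause, although probes in adjacent spots also correlated, at 0.066. The hypothesis that consecutive numbers mark neighbouring or shared transcripts was not tested, since the probes are unnamed.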
